A study of Mus musculus with 8 samples.

How the data were processed

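Transcripts were measured on 8 Affymetrix Mouse Genome arrays, in 4 groups of 2 arrays each: sorted XX pre-granulosa cells, sorted XY Sertoli cells, whole ovaries and whole testes, all at embryonic day 13. Per the labels, the sorted cells were EGFP-positive cells of a transgenic line on a C57BL/6J background, and about 20 ng of total RNA of each sample gave about 2.5 µg of labelled cDNA per array. The deposited values are on the log2 scale, and RMA is named for them in the submitters' processing notes, with no version. The series text names R/maanova and a false discovery rate of 1% for the authors' own test, whose results were not used here. The ranked values were nearly equal within the 4 sorted-cell arrays (largest difference 0.18) and within the 4 gonad arrays (0.15), and the median difference between the 2 sets was 0.38. The sets therefore appear to have been normalized separately, a step that no label records. Values were used as deposited.

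The table held 45101 probe sets, of which 64 were array controls and 45037 were tested. A single gene symbol belonged to 34945 of them, several symbols to 932 and none to 9160. For each gene the probe set with the highest mean over the 8 arrays was taken among those with a single symbol, which gave 18193 genes, 9010 of them with more than 1 probe set. Symbols were compared with a RefSeq gene table of the mouse assembly GRCm38.p6 through the gene identifier for 34741 probe sets and 0 symbols changed. That table was used for names and chromosomes only, and no coordinates are given. A gene is named by its symbol, and its values come from its chosen probe set.

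Means and standard deviations per group were computed from the 2 arrays of each group. Differences were tested with limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group over all 8 arrays, eBayes, two-sided p-values and Benjamini-Hochberg adjustment over the 45037 probe sets, with calls at an adjusted p of 0.01. No covariate was used, and 4 residual degrees of freedom remained. The comparisons were Sertoli minus pre-granulosa, testis minus ovary, Sertoli minus testis, pre-granulosa minus ovary, and Sertoli minus pre-granulosa less testis minus ovary. The word called, and higher or lower with no p beside it, refers to this test. Standard errors are those of the model. Where all arrays of a group read at or under 4.78, the highest value in XX arrays of the 9 probe sets of Eif2s3y, Uty and Kdm5d, the sex-linked genes are given as the smallest difference from that level. For the sorted minus gonad comparisons the printed difference is less the median of all genes, while the p-value tests the difference itself.

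Gene lists were fixed before the data were examined: 34 lists of cell type markers, pathways and cell states, with 519 entries, of which 472 were measured. The 33 lists with at least 3 measured members were tested per comparison with limma's camera at a preset correlation of 0.01, adjusted over the lists and called at 0.05, and again with an estimated correlation and with fry. Camera called 13 lists for Sertoli minus pre-granulosa, 16 for testis minus ovary, 12 for Sertoli minus testis, 11 for pre-granulosa minus ovary and 11 for the difference. With an estimated correlation 2, 3, 0, 0 and 0 lists were called, in the same order. The calls that held were the Sertoli and pre-granulosa lists in both XY minus XX comparisons, and the Y-linked list in testis minus ovary. List members were also adjusted over their list alone.

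Genes to be named were chosen by a rule written before the data were examined. For each comparison it takes the 8 highest and 8 lowest differences among called genes whose groups do not overlap, without clone names and gene models. It adds from each list with a called member up to 4 called and 2 not called members, and 17 fixed identity and marker genes wherever the array has them. Exceptions are stated where they occur. For the difference of the comparisons it takes 5 and 5 called genes, of which there were 0.

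The procedure was tested on simulated data built from the real means and spreads of the probe sets, with 200 changed of 45037 probe sets in each of 10 runs. With the spread of each group as in the data, Sertoli minus pre-granulosa recovered 0.448% of changes of 1 log2 unit, 41.5% of changes of 2 and 86.1% of changes of 4, with 4.4 false calls per run on average. Testis minus ovary recovered 0.149%, 42.1% and 85.9% of the same sizes, with 0.1 false calls per run. For Sertoli minus pre-granulosa, the only comparison in which lists were simulated, the Sertoli list shifted by 1 log2 unit was called in 10 of 10 runs, and 0 lists were called with no change. The simulated noise was independent between probe sets, so these runs cannot show how many lists are falsely called when genes are correlated.

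Alternatives were quantile normalization over all arrays or within each set, median centring, filters on dim probe sets, other forms of moderation, a replicate block, thresholds, omission of each array in turn, omission of probe sets that can match several transcripts, the mean of all probe sets of a gene and the 4 arrays of a comparison alone. A pseudocount had no use because the values are already logarithms. Weights per group, and list members counted under every setting and without pre-granulosa replicate 1, were added after the data had been seen. With 2 arrays per group, outliers within groups and other splits of the samples were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.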

Results

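Transcript levels were measured on 8 whole-transcriptome microarrays of mouse gonads at embryonic day 13, when the testis and the ovary have begun to differ in their tissue organisation. There were 4 groups of 2 arrays. Fluorescent cells sorted from XX gonads are called pre-granulosa cells here and fluorescent cells sorted from XY gonads Sertoli cells, as in the labels, and they are the supporting cells that surround the germ cells. The other groups were whole ovaries and whole testes, with 4 gonads pooled per sample. Each pre-granulosa sample held about 30000 sorted cells and each Sertoli sample about 22000. The labels do not state whether the 2 samples of a group came from separate animals or litters, so each p-value rests on the spread between these samples, pooled over the 4 groups. The standard deviation between replicates (root mean square over probe sets) was 0.531 for pre-granulosa cells, 0.428 for Sertoli cells, 0.299 for ovaries and 0.198 for testes. On average the pooled spread is therefore too low for Sertoli minus pre-granulosa and too high for testis minus ovary. The median log2 value was 5.58 on average over the 4 sorted-cell arrays and 5.97 over the 4 gonad arrays. Replicates correlated across probe sets at 0.944 for pre-granulosa cells, 0.964 for Sertoli cells, 0.984 for ovaries and 0.993 for testes. With 2 arrays per group, the number of arrays limits the precision.

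The first comparison asked which genes distinguish XY from XX supporting cells (Sertoli minus pre-granulosa). Dhh, the hedgehog ligand that Sertoli cells send to the interstitium, stood at 12.27 ± 0.12 in Sertoli cells and 5.78 ± 0.87 in pre-granulosa cells (mean log2 ± SD, n = 2 each), 89.8-fold higher. Foxl2, the transcription factor that maintains granulosa cell identity, was 16.1-fold lower in Sertoli cells (5.31 ± 0.17 against 9.32 ± 0.47), and its neighbouring opposite-strand transcript Foxl2os was 101-fold lower. Amh, the hormone that makes the Müllerian ducts regress, was 6.84-fold higher in Sertoli cells, and Wnt4, a ligand of the ovarian pathway, was 15.2-fold lower. Genes that peak in the G2 and M phases of the cell cycle were higher in Sertoli cells as well, such as Ccnb2, a mitotic cyclin, at 15.6-fold. In all, 485 genes differed, 294 of them higher in Sertoli cells and 191 higher in pre-granulosa cells.

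The sex of the samples was read first. Xist, the RNA that silences an X chromosome, was at least 106-fold lower in Sertoli cells, and the Y-linked genes Eif2s3y, Uty and Kdm5d were higher by at least 5.50, 4.25 and 4.31 log2 units, each against a background level of 4.78. Another Xist probe set was called as well (-6.46, adjusted p = 8.59e-04), and a further one was not (-4.13, adjusted p = 0.0902). The 3 Y-linked genes were the 3 called of 7 Y-linked genes measured, and 3 passed when adjusted over the list alone. The list as a whole was called higher (adjusted p = 0.00189), with adjusted p = 0.174 with an estimated correlation. Among its other members, Uba1y differed by 1.01 and Zfy2 by -0.19, neither called. Neither probe set of Sry, the testis-determining gene, separated XY from XX samples (7.93 ± 0.03 and 7.99 ± 0.18 for the chosen one), so they give no information on Sry. The second one was called higher in sorted cells than in gonads on both sides, by 1.11 and 1.16 with the median of all genes not subtracted (adjusted p = 0.00540 and 0.00517). The background level of 4.78 is the highest value in XX arrays of the 9 probe sets of Eif2s3y, Uty and Kdm5d, which read from 3.11, with a median of 3.59. Background differs between probe sets, since in XX arrays Usp9y read up to 5.17, Uba1y up to 5.30 and Zfy2 up to 6.68. A difference from a group whose arrays all read at or under 4.78 is a difference from background and not an exact size. Usp9y is named after its values were seen.

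Of 23 Sertoli cell genes measured, 15 were higher in Sertoli cells, 0 were lower, and 20 passed when adjusted over the list alone (list adjusted p = 1.24e-21; adjusted p = 0.0130 with an estimated correlation). Besides Dhh, Cbln4, a secreted cerebellin, was higher by 5.46 ± 0.24 (log2 difference ± SE), the cystatin Cst9 by 4.96 ± 0.52 and the collagen chain Col9a3 by 4.89 ± 0.58. Hsd17b3, which makes testosterone from androstenedione, had a difference of 6.88 ± 1.05 that was not called (adjusted p = 0.0190), because its pre-granulosa arrays lay far apart (5.76 ± 2.58). Sox9, the transcription factor of the testis pathway, differed by 1.73 ± 0.37 (adjusted p = 0.0541), with 10.01 ± 0.78 in pre-granulosa cells against 8.24 ± 0.24 in whole ovaries. Of 18 pre-granulosa and ovarian somatic genes, 4 were called, all lower in Sertoli cells, and 12 passed when adjusted over the list alone (list adjusted p = 6.27e-15; adjusted p = 0.0154 with an estimated correlation). The called members were Foxl2, Wnt4, Gng13 (-3.78 ± 0.22) and Sprr2d (-2.37 ± 0.28). Fst, which binds activin, and the transcription factor Irx3 had differences of -6.52 ± 0.95 and -4.77 ± 0.61 that were not called (adjusted p = 0.0159 and 0.0108). A second probe set of Fst with a lower mean was called, at -5.17 (adjusted p = 8.90e-04). Second probe sets of Wnt4 (-2.36, adjusted p = 0.0268), Dhh (0.55, adjusted p = 0.168) and Foxl2 (-0.42, adjusted p = 0.491) were not. Bmp2, at -3.64 ± 0.53, and Rspo1, at -3.35 ± 0.57, were not called either.

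**Figure D1:**
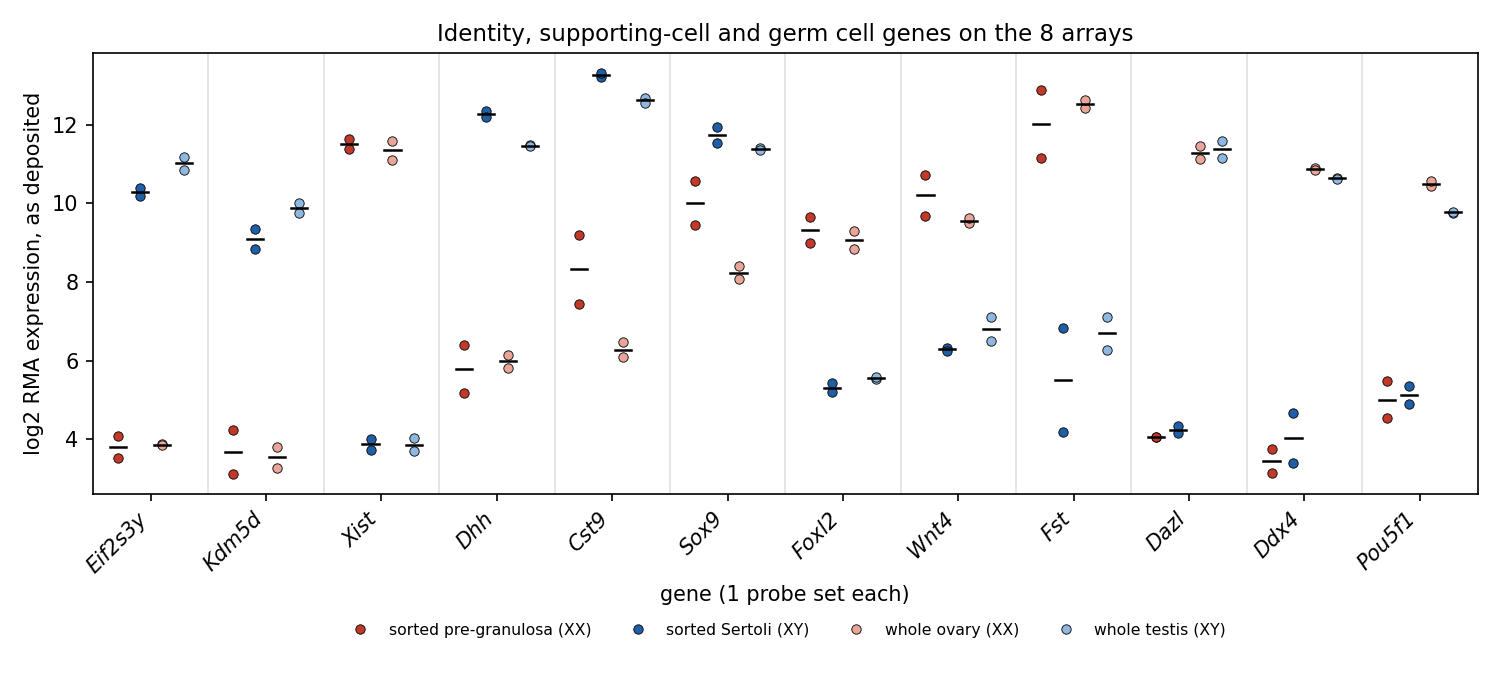
Log2 expression of identity and marker genes on each of the 8 arrays, 1 probe set per gene, with points for arrays and a bar for the mean of each group. Dhh lay at 11.45 or above on every XY array and at 6.39 or below on every XX array, and Ddx4 lay at 10.62 or above in the gonads and at 4.66 or below in sorted cells.

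Cell cycle genes made up the largest group of called genes after the Sertoli genes among the lists. Of 14 G2 and M phase genes, 11 were higher in Sertoli cells and 12 passed when adjusted over the list alone, with a median difference of 2.79 (list adjusted p = 1.56e-15; adjusted p = 0.0981 with an estimated correlation). Bub1, a spindle checkpoint kinase, differed by 4.33 ± 0.44, the mitotic kinase Cdk1 by 3.91 ± 0.37 and the topoisomerase Top2a by 2.98 ± 0.23. Mki67 and Kif11 were not called, at 3.73 ± 0.53 and 1.63 ± 0.49. Of 15 S phase genes, 1 was called, the replication helicase subunit Mcm7 (1.47 ± 0.15). The S phase list as a whole was higher in Sertoli cells (adjusted p = 2.17e-06; adjusted p = 0.179 with an estimated correlation). Pre-granulosa replicate 1, which belongs to the group with the lower values, had the largest excess of 3' over 5' signal of the 8 arrays, at 3.08 log2 units for actin and 3.68 for Gapdh, a sign of shorter RNA. Pre-granulosa replicate 2 had 1.70 and 1.24. Without replicate 1, 11 of the G2 and M phase genes, 15 Sertoli genes and 7 pre-granulosa genes were called, a count added after those ratios had been seen.

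**Figure D2:**
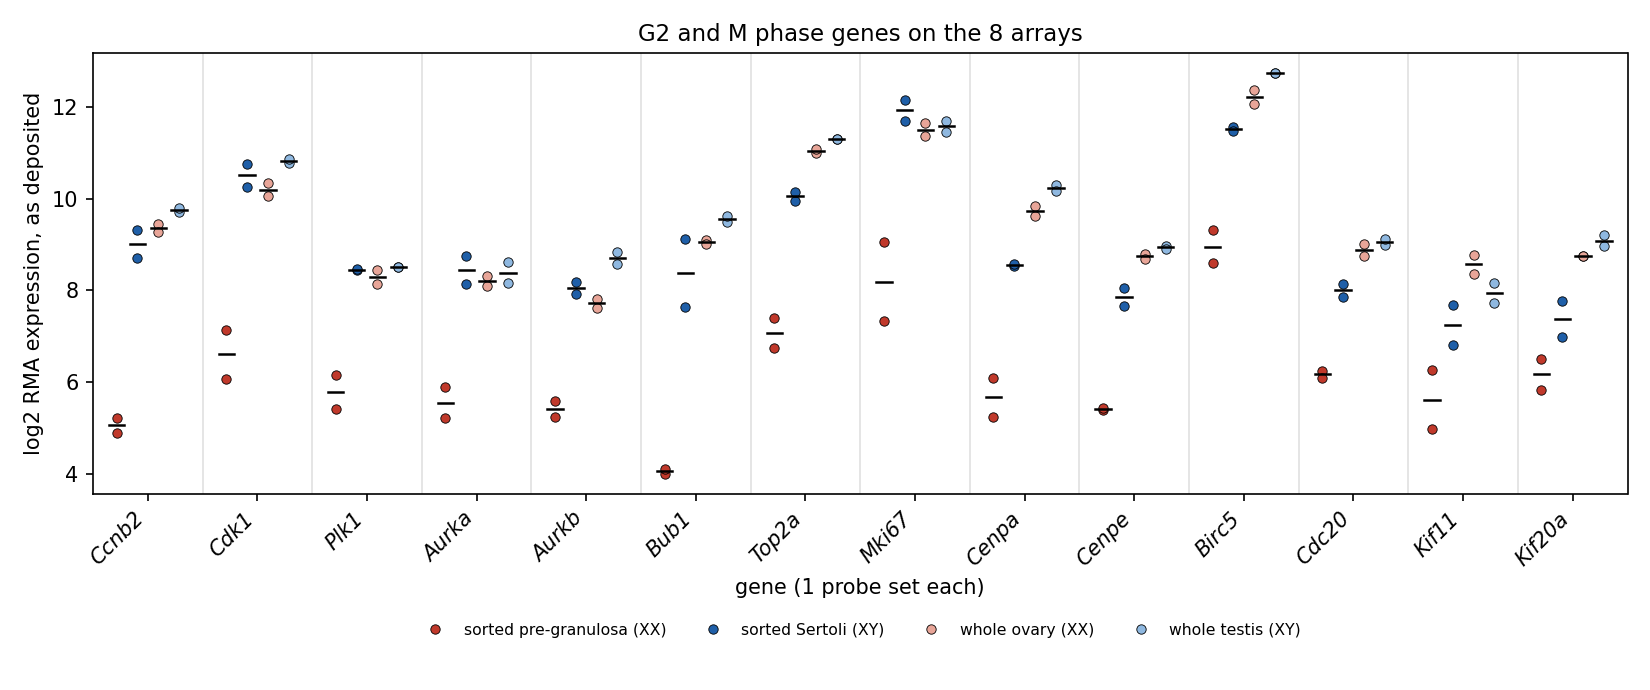
Log2 expression of the 14 measured G2 and M phase genes on each of the 8 arrays, with points for arrays and a bar for the mean of each group. Ccnb2 stood at 5.05 ± 0.23 in pre-granulosa cells and 9.01 ± 0.44 in Sertoli cells, against 9.36 ± 0.11 in ovaries and 9.75 ± 0.07 in testes.

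Signalling genes differed singly. Inhbb, a subunit of inhibin and activin, was 9.77-fold higher in Sertoli cells, and Etv5, a transcription factor of the FGF response, 17.5-fold higher. In the Wnt list 3 of 21 genes were called, Wnt4, Wnt9a (-5.06 ± 0.30) and Sp5 (-2.29 ± 0.21), all lower in Sertoli cells, though the list was not (adjusted p = 0.0629). Of the retinoid genes, Cyp26b1, which degrades retinoic acid, was 7.30-fold higher and Aldh1a1, which makes it, 2.32-fold higher, while Dhrs3, which reduces retinaldehyde, was 9.88-fold lower. Lhx9, a transcription factor of the early gonad, was 21.6-fold lower and the growth factor Igf2 5.54-fold lower. In pre-granulosa cells the growth factor Ereg (-6.29 ± 0.24, Sertoli minus pre-granulosa), the kinase Dclk1 (-5.88 ± 0.40) and Drp2, a dystrophin relative (-5.29 ± 0.19), were among the genes with the largest excess. In Sertoli cells Rtn4rl1 (6.27 ± 0.40), the collagen Col14a1 (5.98 ± 0.58) and Ankrd63 (5.68 ± 0.32) were. Adm, which encodes adrenomedullin, was lower in Sertoli cells (-3.15 ± 0.26) and was the 1 called gene of 10 in the hypoxia list (list adjusted p = 0.0281; adjusted p = 0.227 with an estimated correlation). That list was not called without pre-granulosa replicate 2 or Sertoli replicate 2 (adjusted p = 0.160 and 0.0779).

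Markers of other cell types were read beside these groups. Ddx4, a germ cell gene, stood at 3.44 ± 0.44 in pre-granulosa and 4.03 ± 0.89 in Sertoli cells against 10.87 ± 0.02 in ovaries, and 0 of 27 germ cell genes were called by limma between the sorted cell types (list adjusted p = 0.418). Rec8, a meiotic cohesin subunit, and Sycp3, of the synaptonemal complex, were nonetheless lower in Sertoli than in pre-granulosa cells (-3.56 ± 0.29 and -2.31 ± 0.26). Macrophage genes were higher in Sertoli samples as a list (adjusted p = 6.12e-04; adjusted p = 0.435 with an estimated correlation), with C1qb called and Csf1r at 6.54 and 10.86 in the 2 Sertoli arrays. Endothelial genes were higher too (adjusted p = 0.00357; adjusted p = 0.377 with an estimated correlation), with Robo4 called of 19. Basement membrane genes, with Col18a1 and Dag1 called of 17, were higher in Sertoli cells (adjusted p = 0.0145; adjusted p = 0.199 with an estimated correlation). The steroidogenic, interstitial, glycolysis and immediate early lists were called higher with 0 members called (adjusted p = 0.0239, 0.0387, 0.0108 and 0.0240). With an estimated correlation their adjusted p were 0.555, 0.283, 0.227 and 0.278. Without pre-granulosa replicate 1 the endothelial, interstitial and immediate early lists were no longer called (adjusted p = 0.344, 0.440 and 0.166), and without pre-granulosa replicate 2 the steroidogenic list was not (0.189). Without Sertoli replicate 1 the basement membrane, interstitial and glycolysis lists were not called (0.0567, 0.183 and 0.0667), nor without Sertoli replicate 2 the steroidogenic and immediate early lists (0.110 and 0.102).

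Genes were tested with limma over all 8 arrays, with 1 mean per group and calls at an adjusted p of 0.01. The count of 485 rests on the spread pooled over the 4 groups: with the 4 sorted arrays alone limma called 0 genes (lowest adjusted p = 0.0614, 2673 genes at an unadjusted p under 0.05), with a weight per group 174, and without moderation 8. The count was 64 without Sertoli replicate 2, 187 without Sertoli replicate 1, 71 without either testis array, 129 without either ovary array, 916 without pre-granulosa replicate 2 and 511 without pre-granulosa replicate 1, of which 314 were among the 485. Over the same omissions the called Sertoli genes ranged from 4 (without Sertoli replicate 2) to 16 (without pre-granulosa replicate 2), the G2 and M phase genes from 1 (without either testis array) to 11 and the pre-granulosa genes from 0 (without Sertoli replicate 2) to 7 (without pre-granulosa replicate 1). Without any one of the Sertoli, ovary and testis arrays 0 genes of the S phase, macrophage, endothelial, basement membrane, FGF, retinoid, insulin and meiotic lists were called, and 1 of the Wnt list.

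The second comparison asked the same question of whole organs (testis minus ovary). Sertoli cell genes were again higher on the XY side: Dhh by 5.50 ± 0.38, Cbln4 by 6.07 ± 0.24, Cst9 by 6.35 ± 0.52 and Ptgds, which makes prostaglandin D2, by 6.08 ± 0.33 (log2 difference ± SE, n = 2 against 2). Genes of steroid synthesis in fetal Leydig cells were higher in testes, with Cyp17a1 at 67.4-fold, Cyp11a1 at 48.9-fold and Hsd3b1 at 9.69-fold. In ovaries Foxl2 was higher (-3.52 ± 0.27, testis minus ovary), as were Rec8 (-4.02 ± 0.29), the calcium-binding protein gene Calb1 (-4.73 ± 0.15) and Cdx2, a homeobox gene (-4.18 ± 0.25). In all, 64 genes differed, 43 higher in testes and 21 higher in ovaries. Both ovary arrays had a larger excess of 3' over 5' signal than both testis arrays, at 2.33 and 2.18 against 1.57 and 1.96 log2 units for actin and 1.55 and 1.40 against 0.72 and 0.95 for Gapdh.

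Xist was at least 95.0-fold lower in testes, and 2 of 7 Y-linked genes were called, Eif2s3y at 6.24 or more and Kdm5d at 5.10 or more against the background level of 4.78, with 4 when adjusted over the list alone (list adjusted p = 3.06e-08; adjusted p = 0.0408 with an estimated correlation). Of 23 Sertoli cell genes 8 were higher in testes and 18 passed when adjusted over the list alone (list adjusted p = 1.42e-34; adjusted p = 0.00515 with an estimated correlation). Sox9 differed by 3.15 ± 0.37 and was not called (adjusted p = 0.0263), and Amh differed by 0.67 ± 0.17 (adjusted p = 0.231). Of 18 pre-granulosa genes 2 were lower in testes, Foxl2 and Gng13 (-3.29 ± 0.22), and 10 passed when adjusted over the list alone (list adjusted p = 9.76e-14; adjusted p = 0.0177 with an estimated correlation). Wnt4 (-2.74 ± 0.37), Fst (-5.85 ± 0.95), Bmp2 (-2.59 ± 0.53) and Rspo1 (-2.68 ± 0.57) were not called (adjusted p = 0.0409, 0.0735, 0.140 and 0.152). The second probe set of Fst was called lower in testes, at -2.99 (adjusted p = 0.00857). Those of Foxl2 (-0.60, adjusted p = 0.589) and Dhh (0.44, adjusted p = 0.536) were not called. Of Xist, another probe set was called (-5.37, adjusted p = 0.00256) and a further one was not (-6.63, adjusted p = 0.0720).

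By camera, lists of germ cell genes differed between the organs at the preset correlation and not with an estimated one. Fry called the male germ cell and meiotic lists (adjusted p = 0.00232 and 0.00536) and not the general germ cell list (0.0840). Lefty2, a Nodal antagonist, was 12.9-fold higher in testes and was the 1 called of 6 male germ cell genes, of which 4 passed when adjusted over the list alone (list adjusted p = 7.83e-06; adjusted p = 0.102 with an estimated correlation). Meiotic prophase genes were lower in testes as a list, with 1 of 21 called, Rec8, and 2 adjusted over the list alone (list adjusted p = 7.83e-06, and 0.110 with an estimated correlation). Rec8 read 11.29 and 10.42 in sorted pre-granulosa cells against 9.82 and 9.98 in ovaries, while Ddx4 read 3.13 and 3.75 in those sorted cells. The Rec8 difference therefore cannot be assigned to germ cells. Stra8, which is needed for entry into meiosis, stood at 7.89 ± 0.53 in ovaries and 5.50 ± 0.11 in testes and was not called (adjusted p = 0.0249). The general germ cell list was lower in testes with 0 of 27 called by limma (list adjusted p = 0.00550; adjusted p = 0.281 with an estimated correlation), and Ddx4 and Pou5f1 differed by -0.23 and -0.73. Cyp26b1 was 12.1-fold higher in testes.

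Of 9 steroidogenic genes 3 were called higher in testes and 7 passed when adjusted over the list alone (list adjusted p = 4.37e-13, and 0.110 with an estimated correlation). Star, which carries cholesterol into mitochondria, was not called at 3.17 ± 0.52. The interstitial, hedgehog response, Notch, cholesterol and FGF lists were higher in testes with 0 members called (adjusted p = 1.17e-04, 0.00459, 0.00272, 0.0314 and 0.0433). With an estimated correlation their adjusted p were 0.110, 0.110, 0.144, 0.163 and 0.170. The G2 and M phase list was also higher in testes with 0 of 14 called and a median of 0.30 (adjusted p = 0.00374; adjusted p = 0.281 with an estimated correlation). Coelomic surface epithelium genes were lower in testes as a list, with a median of -0.98, 0 of 10 called by limma and 5 passing when adjusted over the list alone (list adjusted p = 5.96e-07, and 0.108 with an estimated correlation). The Wnt and CDK inhibitor lists were lower in testes (adjusted p = 0.0433 and 0.0433; adjusted p = 0.170 and 0.327 with an estimated correlation), with Sp5 the 1 called Wnt gene (-2.63 ± 0.21). The calls of the Wnt, FGF, CDK inhibitor and cholesterol lists each ended without single arrays. The highest adjusted p were 0.125 (Wnt, without either Sertoli array), 0.144 and 0.0967 (FGF without ovary replicate 2, cholesterol without testis replicate 1) and 0.0867 (CDK inhibitors, without ovary replicate 1).

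The count of 64 fell whichever gonad or Sertoli array was left out, and each omission also took a residual degree of freedom. Without either testis array limma called 0 genes (1084 and 1276 at an unadjusted p under 0.05 without replicate 1 and 2), without either ovary array also 0 (1474 and 1478), without either Sertoli array 20, and with the 4 gonad arrays alone 53, of which 30 were among the 64. Those 4 omissions of a gonad array likewise left 0 called members in every list named here, and without either Sertoli array 3 Sertoli genes, 0 pre-granulosa genes and 2 steroidogenic genes were called. Without either pre-granulosa array the called steroidogenic genes were 1 and the called pre-granulosa genes 3, and a weight per group gave 257 genes in all.

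The 2 XY minus XX comparisons shared 23 genes higher in XY, where 0.695 would be shared by independent lists, and 15 higher in XX, against 0.220. Among the former were Dhh, Cbln4, Cst9, Ptgds, Tesc, Cyp26b1 and Gdnf, the last a growth factor of spermatogonial stem cells, and among the latter Foxl2, Ereg, Adm, Rec8, Calb1 and Egfl6. Ptgds, Tesc, Gdnf, Calb1 and Egfl6 were named here after their values in the sorted cells were seen. The numbers for independent lists are a low baseline, because both comparisons used the same pooled spread of each gene. No gene was called in opposite directions, and 431 of the 485 genes called in sorted cells (88.9%) and 60 of the 64 called in gonads had the same sign in the other comparison. Across 18193 genes, which are not independent replicates, the log2 differences correlated at 0.515 (Pearson) and 0.346 (Spearman). A setting in which either comparison has 0 calls gives 0 shared genes by construction. Without either testis or either ovary array the shared counts were 0 and 0, and without Sertoli replicate 1 they were 7 and 5, and without Sertoli replicate 2 they were 4 and 5.

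**Figure D3:**
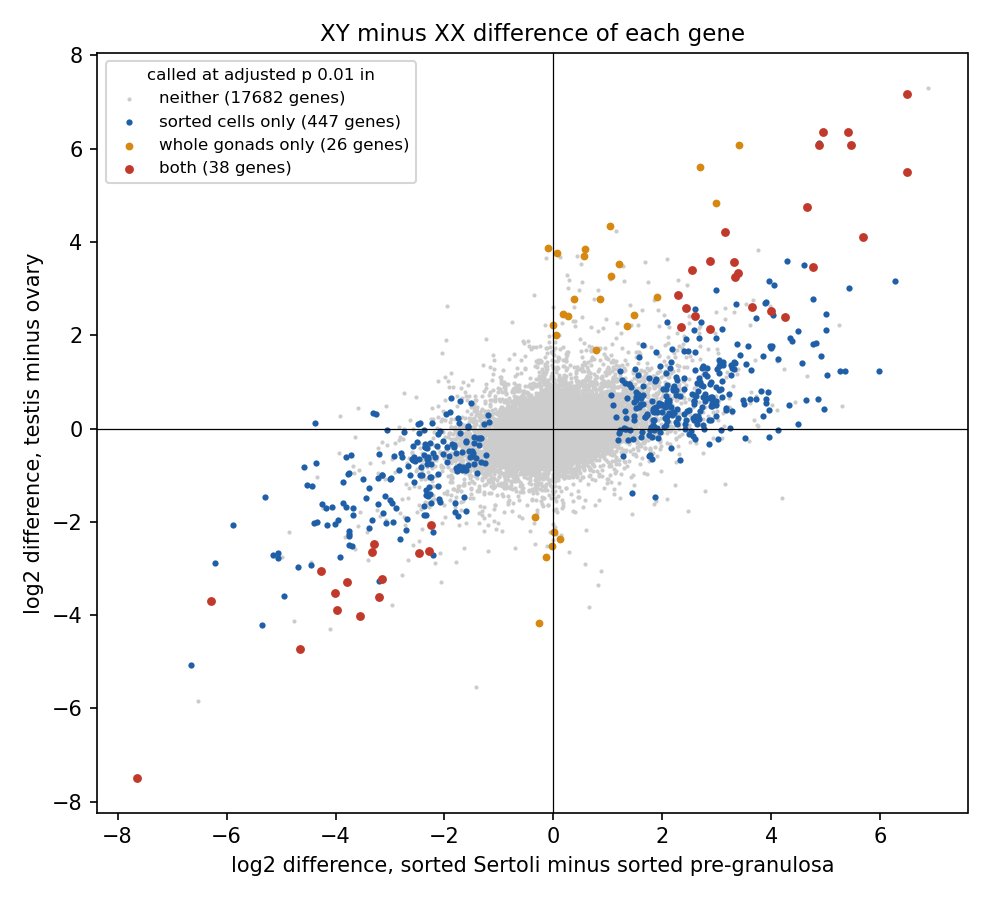
Log2 difference of each of 18193 genes between testes and ovaries (vertical axis) against that between Sertoli and pre-granulosa cells (horizontal axis), coloured by where the gene was called. The 38 genes called in both lie in the 2 quadrants of equal sign, beside 447 called only in sorted cells and 26 only in gonads.

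The difference between these comparisons, sorted cells minus gonads, was tested directly. Limma called 0 genes at an adjusted p of 0.01 (2367 at an unadjusted p under 0.05, 62 at an adjusted p of 0.05). In every other setting run for this difference 0 genes passed 0.01, and the 4-array fits could not be run for it. Amh was among the 62, with an XY minus XX difference 2.11 ± 0.24 larger in sorted cells (adjusted p = 0.0479). Others, named after their values were seen, were Ccnb2 (3.58 ± 0.34) and the cohesion factor gene Cdca5 (4.15 ± 0.47) on the side of the sorted cells, and Lefty2 (-3.14 ± 0.32), Lhx9 (-3.20 ± 0.29) and Bmp5 (-4.50 ± 0.40) on the other. Sox9 differed by -1.42 ± 0.52 between the comparisons and Stra8 by 2.38 ± 0.39, neither called (adjusted p = 0.381 and 0.0853). The Sertoli list was not called by camera (median 0.21, adjusted p = 0.279), while 6 of 23 members were higher when adjusted over the list alone and fry gave an adjusted p of 0.0288. The G2 and M phase list was called, with a median of 2.44 and 12 of 14 members when adjusted over the list alone (adjusted p = 5.29e-16; adjusted p = 0.141 with an estimated correlation).

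The third comparison asked what the sort removed and kept on the XY side (Sertoli minus testis). The sorted-cell and gonad arrays had different value distributions and appear to have been normalized separately, which the labels do not state, so the differences of this and the next comparison are given less the median of all genes, which was -0.29 here. Germ cell genes were far lower in sorted cells: Dazl, an RNA-binding protein of germ cells, by -6.84 ± 0.21, Ddx4 by -6.31 ± 0.42 and Pou5f1 by -4.37 ± 0.33 (log2 difference ± SE, n = 2 against 2). Interstitial genes were lower as well, with the growth factor receptor Pdgfra at -5.20 ± 0.29 and the transcription factor Tcf21 at -4.32 ± 0.33. Higher in sorted cells were Amh (1.35 ± 0.17), the transcription factor Sox10 (2.81 ± 0.21) and immediate early genes such as Fos (4.19 ± 0.40). In all, 1765 genes differed, 180 higher in Sertoli cells and 1585 lower, and with the 8 arrays quantile normalized together 1027 differed, 369 higher and 658 lower. Both Sertoli arrays had a larger excess of 3' over 5' signal than both testis arrays, at 2.17 and 2.51 against 1.57 and 1.96 log2 units for actin and 1.94 and 2.69 against 0.72 and 0.95 for Gapdh, so RNA quality differed along with the sort and was not separated from it.

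Of 27 germ cell genes 17 were lower in Sertoli cells than in testes and 22 passed when adjusted over the list alone (list adjusted p = 4.85e-10; adjusted p = 0.125 with an estimated correlation). Of 16 interstitial genes 10 were lower, and 13 over the list alone (adjusted p = 2.46e-06; adjusted p = 0.125 with an estimated correlation). The same held for 5 of 19 endothelial genes, such as Emcn (-2.97 ± 0.51) and Kdr (-1.28 ± 0.13), with 9 over the list alone (adjusted p = 0.00305; adjusted p = 0.396 with an estimated correlation). Steroidogenic genes (2 of 9, 6 over the list alone; Hsd3b1 -1.67, Mc2r -3.53) and hedgehog response genes (3 of 9, 7 over the list alone; Gli1 -2.18, Gas1 -3.43) were lower (adjusted p = 0.00677 and 0.00677). With an estimated correlation their adjusted p were 0.511 and 0.174. Meiotic genes (7 of 21), male germ cell genes (5 of 6) and insulin and IGF pathway genes (7 of 14, Igf2 -2.63, Igf1 -2.12) were also lower as lists (adjusted p = 0.00204, 0.0231 and 0.00222). With an estimated correlation these became adjusted p = 0.266, 0.266 and 0.130, and the male germ cell list was not called without either pre-granulosa array (adjusted p = 0.0873).

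Sertoli cell genes were higher in the sorted cells as a list, with 4 of 23 called, Sox10, Tesc (2.28 ± 0.15), Mro (2.18 ± 0.21) and Amh, and 4 over the list alone (adjusted p = 1.91e-07; adjusted p = 0.107 with an estimated correlation). Sox9 and Dhh differed by 0.65 ± 0.37 and 1.09 ± 0.38, neither called. Of 26 immediate early genes, which respond to stimulation and stress within minutes, 5 were higher and 1 lower, with 6 and 1 over the list alone (adjusted p = 4.73e-07; adjusted p = 0.125 with an estimated correlation). Egr2, outside the list, was higher as well (5.18 ± 0.24), and so were Tmem86b and Hnf4a, which lay at background in testes, by at least 3.21 and 2.75 with the median of all genes not subtracted. Glycolysis genes were higher with Hk1 called (2.29 ± 0.28) and ribosomal protein genes lower with 0 called by limma (adjusted p = 0.0360 and 0.0231; adjusted p = 0.273 and 0.246 with an estimated correlation). The glycolysis call ended without Sertoli replicate 1 or either pre-granulosa array (adjusted p = 0.108 and 0.0577) and the ribosomal one without testis replicate 1 (0.0536). The G2 and M phase list was not called (median -0.60, adjusted p = 0.103), with 2 of 14 members lower, Cenpe and Cdc20, 6 lower when adjusted over the list alone and a fry adjusted p of 0.00717. The list-alone adjustment and fry test the difference with the median of all genes not subtracted. Fry also called widely used reference genes lower here (adjusted p = 0.00278). The called G2 and M phase members were 0 by limma when the 8 arrays were quantile normalized together.

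Without either testis array limma called 0 genes in this comparison (5086 and 5098 at an unadjusted p under 0.05), and 0 members of any list. The count was 599 without Sertoli replicate 1, 549 without Sertoli replicate 2, 776 without either ovary array and 3084 without either pre-granulosa array, and over those 6 omissions the called germ cell genes numbered 12 (without Sertoli replicate 1) to 19, the immediate early genes 2 (without Sertoli replicate 2) to 8, the endothelial genes 2 (without any Sertoli or ovary array) to 10 and the Sertoli genes 2 (without Sertoli replicate 2) to 5, each upper end without either pre-granulosa array. Without Sertoli replicate 2 the called meiotic, insulin and male germ cell genes were 3, 1 and 3, without Sertoli replicate 1 they were 2, 2 and 3, and without either ovary array 4, 3 and 3. The G2 and M phase genes were 6 without either pre-granulosa array and 0 without Sertoli replicate 1 or either ovary array, and the steroidogenic genes 1 without Sertoli replicate 1.

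The fourth comparison asked the same on the XX side (pre-granulosa minus ovary), where the median of all genes was -0.40. Germ cell genes were again lower in sorted cells, Ddx4 by -7.03 ± 0.42, Dazl by -6.85 ± 0.21, Lin28a by -5.57 ± 0.33 and Pou5f1 by -5.11 ± 0.33. Meiotic genes were lower with them, Meioc by -5.87 ± 0.48 and Stra8 by -2.21 ± 0.28. G2 and M phase genes were lower in sorted pre-granulosa cells, Bub1 by -4.61 ± 0.44 and Top2a by -3.57 ± 0.23. Higher in sorted cells were Egr2 (5.51 ± 0.24), Fos (4.05 ± 0.40) and Egr1 (3.21 ± 0.20). In all, 1751 genes differed, 92 higher in pre-granulosa cells and 1659 lower, and with the 8 arrays quantile normalized together 843 differed, 214 higher and 629 lower.

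Of 27 germ cell genes 20 were lower and 23 passed when adjusted over the list alone, of 21 meiotic genes 9 and 13, of 16 interstitial genes 10 and 14, and of 19 endothelial genes 10 and 14. All 4 lists were called (adjusted p = 2.48e-12, 1.03e-04, 8.09e-07 and 5.25e-06; adjusted p = 0.118, 0.182, 0.118 and 0.233 with an estimated correlation). Pdgfra differed by -3.49 ± 0.29 and the vascular gene Plvap by -2.30 ± 0.22. Macrophage genes were lower, 4 of 15, such as Mrc1 (-3.10 ± 0.44) and Lyz2 (-1.88 ± 0.19), as were 2 of 13 Notch pathway genes, Hey2 and Notch3 (adjusted p = 0.0302 for both lists; adjusted p = 0.601 and 0.253 with an estimated correlation). Neither was called without pre-granulosa replicate 1 (adjusted p = 0.169 and 0.164) or ovary replicate 2 (0.0639 and 0.0522), nor the macrophage list without pre-granulosa replicate 2 (0.0919). G2 and M phase genes were lower in 13 of 14 cases, all 14 over the list alone, and S phase genes in 8 of 15, with 14 over the list alone (adjusted p = 1.10e-08 and 2.76e-05; adjusted p = 0.159 and 0.182 with an estimated correlation). Pre-granulosa replicate 1, the array with the largest 3' excess, lies on the lower side here too, and without it 12 G2 and M phase and 11 S phase genes were called.

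Pre-granulosa genes were higher in the sorted cells as a list (median 0.58, adjusted p = 0.00972; adjusted p = 0.172 with an estimated correlation), with 1 of 18 called, Sprr2d (2.64 ± 0.28). Foxl2, Wnt4 and Fst differed by 0.64, 1.05 and -0.12, none called. The second probe set of Fst was called higher in pre-granulosa cells, at 1.91 with the median of all genes not subtracted (adjusted p = 0.00504), so the call of Fst depended on the probe set. The Sertoli list was higher as well (median 0.58, adjusted p = 5.41e-05; adjusted p = 0.118 with an estimated correlation), although 1 member was called higher, the defensin Defb19 (2.04 ± 0.21), and 3 lower, Inhbb (-1.69 ± 0.20), Dmrt1 (-1.37 ± 0.29) and Amh (-0.66 ± 0.17). With the 8 arrays quantile normalized together 5 Sertoli genes were called higher and 1 lower. Without pre-granulosa replicate 2 neither the pre-granulosa nor the Sertoli list was called (adjusted p = 0.0859 and 0.0559). Of 26 immediate early genes 6 were higher, with 7 over the list alone (adjusted p = 1.07e-05; adjusted p = 0.153 with an estimated correlation). Fos, Egr1, Nr4a1 and Klf4 were called higher in both sorted cell types, Klf4 being named after its values were seen.

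With the 4 arrays of this comparison alone limma called 0 genes (lowest adjusted p = 0.0189, 6436 at an unadjusted p under 0.05). The count was 80 without ovary replicate 2, 138 without ovary replicate 1, 377 without either testis array and 2434 without pre-granulosa replicate 2. Called members of the germ cell, G2 and M phase, interstitial, endothelial, S phase, immediate early, meiotic and macrophage lists numbered 7, 1, 1, 1, 0, 0, 1 and 0 without ovary replicate 2, in that order, 10, 4, 3, 1, 0, 0, 1 and 0 without ovary replicate 1 and 14, 8, 5, 4, 2, 1, 7 and 1 without either testis array.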

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

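The test of each list's difference between the comparisons was planned before the data were examined, while the tests of explanations for the 3 patterns were chosen only after the results had been seen. The XY minus XX difference of 11 gene lists differed between sorted cells and gonads by limma's camera. With an estimated correlation 0 of them did, so all 11 camera calls rest on the preset correlation. Fry, which does not compare a list with the other genes, called 12 of the 33 lists for this difference. The G2 and M phase (fry adjusted p = 0.0105) and S phase lists (0.0151) were among them. Of the 11, the germ cell (0.0752), endothelial (0.101) and macrophage lists (0.0826) were not.

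G2 and M phase genes had an XY minus XX difference 2.44 larger in sorted cells than in gonads (median over 14 genes, adjusted p = 5.29e-16; adjusted p = 0.141 with an estimated correlation), and S phase genes one 1.33 larger (adjusted p = 7.22e-07; 0.141). Poor RNA of pre-granulosa replicate 1 alone is argued against, because replicate 2 by itself lay at a median of -2.73 from the Sertoli mean, with quartiles of -3.18 and -2.26, and below both Sertoli arrays in 14 of 14 genes. Germ or interstitial cells in the Sertoli sort are argued against too, because their genes had a median Sertoli minus testis difference of -3.17 and an upper quartile of -1.46, below the lower quartile of the G2 and M phase genes (-0.91). Macrophages or endothelial cells in that sort, which a clean EGFP gate would remove, stay open. Their genes together had a median of -0.33 and quartiles of -1.15 and 0.27 that span those of the G2 and M phase genes. Taken apart, the macrophage list had a median of 0.27 and the endothelial list one of -1.09, against -0.60 for the G2 and M phase genes. A lower share of cycling cells among XX than XY supporting cells may be the reason, as a hypothesis, but the CDK inhibitor genes (median -0.15, adjusted p = 0.373) did not decide it.

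Immediate early genes were higher in both sorted cell types than in the gonads, a list result that was lost with an estimated correlation (adjusted p = 0.125 and 0.153). Camera compares a list with all other genes, so a shift shared by all genes could not make its call. A shift from separate normalization that varies with the expression level is argued against as the whole cause. With the 8 arrays quantile normalized together the list was still higher in both by camera (the larger adjusted p = 4.74e-05). Purification of supporting cells stays open, since the median of these genes exceeded that of the Sertoli genes by only 0.12 in Sertoli minus testis, with overlapping quartiles. Handling during dissociation and sorting stays open as well: the 4 genes called higher in both sorted cell types restate the pattern and decide nothing, and handling and sorting cannot be told apart because every sorted sample and no gonad sample went through them. A biological difference between supporting cells and whole gonads was not tested apart from these.

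Sertoli cell genes were higher as a list in sorted pre-granulosa cells than in ovaries (median 0.58), a result lost with an estimated correlation (adjusted p = 0.118) and without pre-granulosa replicate 2 (adjusted p = 0.0559). A shift from separate normalization that varies with the expression level is again argued against as the whole cause. By camera the list was higher with the 8 arrays quantile normalized together (adjusted p = 0.00275). XY cells carried into the XX sort stay open. Eif2s3y, Uty and Kdm5d allowed XY shares of up to 1.13%, 2.20% and 2.49%. These are upper limits that count background as signal. Limma called none of these genes in pre-granulosa minus ovary (-0.060, 0.11 and 0.14 with the median of all genes not subtracted, adjusted p = 0.870, 0.828 and 0.829). At the highest share the excess over ovary was 1.30 times what carry-in brings in the median of 23 genes, with quartiles of 0.301 and 3.82. A first version used the 19 genes above the ovary level, a selection by the result, and the tighter Eif2s3y limit, which was widened after its result had been seen. Those 19 gave a median log2 ratio of 1.13 with the wider limit (lower quartile -0.11, 14 genes above 0) and 2.27 with the tighter (1.03, 17 genes). Over all 23 the tighter limit, which the same share would also have to meet, gave a median of 2.86 times. Its quartiles were 0.663 and 8.42 times, so the tighter limit did not exclude carry-in either. Low Sertoli gene transcripts of the XX supporting cells themselves, raised as the sort enriched those cells, are consistent with a difference of 0.00230 between the medians of the Sertoli and pre-granulosa lists, and both explanations stay open.

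Between sorted cells and gonads the XY minus XX difference of the pre-granulosa list differed by a median of -0.66 (adjusted p = 0.00241; 0.141 with an estimated correlation). For germ cell genes it differed by 0.71 (0.00384; 0.340) and was not called without pre-granulosa replicate 2 (0.0974). For male germ cell genes it was -1.28 (3.13e-04; 0.141). Steroidogenic genes gave -1.91 (2.60e-06; 0.264). Hedgehog receptors and response genes gave -0.63 (3.13e-04; 0.141). Endothelial genes gave 0.85 (0.00241; 0.386), no longer called without pre-granulosa replicate 1 (0.299). Macrophage genes gave 1.34 (7.69e-05; 0.386). Insulin and IGF pathway genes gave -0.60 (0.00717; 0.151), not called without pre-granulosa replicate 2 (0.0575). Glycolysis genes gave 0.73 (7.97e-04; 0.141).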

How the results depend on the processing

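Counts of called genes and probe sets depended heavily on how the spread was estimated, while named genes seldom changed direction. Named genes were followed under 14 settings: the 3 normalizations, the replicate block, the mean of all probe sets, weights per group and the omission of each array, but not the other spread estimates, filters, thresholds or the 4-array fits. Of these 6440 values, 4974 kept their side of the threshold (48 of them, not called, changed sign), 1223 were no longer called, 241 became called and 2 reversed. The 63 list calls were followed under 14 settings, lists not called were not, and of these results 761 kept their side of the threshold and 121 were no longer called, and of the counts 211 stayed within 1.5 times and 133 moved. Except where the construction of an alternative shows it, the cause was not tested. As reported, 485 genes (816 probe sets) were called for Sertoli minus pre-granulosa, 64 (97) for testis minus ovary, 1765 (3890) for Sertoli minus testis, 1751 (3728) for pre-granulosa minus ovary and 0 (0) for the difference, which is the order used here. Each list of counts gives genes, with probe sets in parentheses.

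Without moderation of the spread by limma the counts were 8 (13), 0 (0), 310 (657) and 328 (610); for testis minus ovary 1887 genes then had an unadjusted p under 0.05 and the lowest adjusted p was 0.0173. At an adjusted p of 0.05 they were 1343 (2476), 209 (319), 4788 (10818), 4983 (11079) and 62 (113), with 79 genes shared as higher in XY and 56 as higher in XX, against 23 and 15. With only the 4 arrays of the comparison, which leaves 2 residual degrees of freedom, Sertoli minus pre-granulosa gave 0 (0), with 2673 genes at an unadjusted p under 0.05, and pre-granulosa minus ovary 0 (0), with 6436. With the mean of all probe sets of a gene, which also leaves fewer tests, the genes were 754, 137, 2752 and 2632, and 47 and 35 were shared. The 2 reversals arose there: Gata4 in Sertoli minus testis went from 0.97, not called, to -0.76, called, and the called Nid1 in pre-granulosa minus ovary from -1.48 to 0.044, not called. With the 8 arrays quantile normalized together Sertoli minus testis gave 1027 (2469) and pre-granulosa minus ovary 843 (2116), and with each array centred on its median the latter gave 982 (2482). With probe sets under the median mean left out, which removes tests, the probe sets were 2481 and 2389.

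A block for the replicate number gave 209 (341), 13 (17), 966 (2190) and 922 (1897), with 5 and 4 shared genes. Whether the numbers pair samples across groups is not known. The replicate differences of any 2 groups correlated at -0.156 to 0.049, which gave no sign of pairing, so the samples were taken as unpaired. The block also spent a degree of freedom. Weights per group, added after the data had been seen, were 0.430 for pre-granulosa, 0.727 for Sertoli, 1.33 for ovary and 2.41 for testis arrays; they gave 174 (264), 257 (394), 3111 (6746) and 989 (1947), with 48 and 35 shared genes. With an estimated correlation camera called 2, 3, 0, 0 and 0 gene lists, against 13, 16, 12, 11 and 11. In the same order fry called 19, 17, 28, 29 and 12 lists, and 31, 23, 33, 32 and 26 in either direction. In the sorted minus gonad comparisons fry tests differences with the median of all genes not subtracted. Counts of list members under each setting were also added after the data had been seen.

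Leaving out 1 array at a time, the lone array of a group was assumed to vary like the other groups. Sertoli minus pre-granulosa then ranged from 64 genes without Sertoli replicate 2 to 916 without pre-granulosa replicate 2 (probe sets 108 to 1588), and gave 71 without either testis array, 129 without either ovary array and 187 without Sertoli replicate 1. Testis minus ovary ranged from 0 genes without any one of its own 4 arrays to 65 (probe sets 0 to 93; over the counts that moved, genes 0 to 20 and probe sets 0 to 28), and gave 20 without either Sertoli array. Sertoli minus testis ranged from 0 without either testis array to 3084 without either pre-granulosa array (probe sets 0 to 6556), with 599 and 549 without Sertoli replicates 1 and 2 and 776 without either ovary array. Pre-granulosa minus ovary ranged from 80 without ovary replicate 2 to 2434 (probe sets 139 to 4714; over those that moved, 80 to 377 and 139 to 717), with 138 without ovary replicate 1 and 377 without either testis array. For the difference it was 0 genes throughout and 0 to 2 probe sets, 2 without Sertoli replicate 2. Shared genes ranged from 0 to 33 (higher in XY; 0 to 7 over those that moved) and 0 to 15 (higher in XX; 0 to 5), at 0 without any one testis or ovary array. The correlation of the 2 XY minus XX differences across genes, 0.515, ranged from 0.377 without pre-granulosa replicate 1 to 0.553.

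Signal over background sets a further limit. The 9 probe sets of Eif2s3y, Uty and Kdm5d reached up to 4.78 in XX arrays, and 31.1% of the tested probe sets had a mean at or under that value, so that a missing call there says little. Other Y-linked genes read higher in XX arrays, Zfy2 up to 6.68, so background is not the same for every probe set and that share is no exact limit. A pseudocount was planned but not run because the values are logarithms.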

Other observations

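Some genes called in neither XY minus XX comparison changed between gonads and sorted cells. The coelomic surface epithelium gene Upk3b was lower in Sertoli cells than in testes (-3.35 ± 0.14, log2 difference less the median of all genes ± SE, n = 2 against 2) and in pre-granulosa cells than in ovaries (-4.56 ± 0.14), and so was Lrrn4 (-2.62 and -2.85). Of 10 such genes 4 were lower and 1 higher, Krt18 (1.85 ± 0.25), in the first case and 3 lower in the second (list adjusted p = 0.310 and 0.158, neither called). Embryonic globins and red cell genes were lower in both sorted cell types, with 5 and 6 of 11 erythroid genes called, among them Hba-x (-5.16 and -3.98) and Slc4a1 (-3.38 and -3.65), though the list was not called (adjusted p = 0.140 and 0.0651). Of 21 genes of the Wnt list 5 were lower and 1 higher in Sertoli cells, and 4 lower and 0 higher in pre-granulosa cells. Dkk1 (-4.49 and -3.51) and Sfrp1 (-3.28 and -3.47) were lower in both, with the list not called (adjusted p = 0.813 and 0.536). Nid2, a basement membrane linker, was lower in both (-3.64 and -4.20), with that list not called either (adjusted p = 0.813 and 0.381). Six4, a transcription factor of the early gonad, was lower in both (-4.35 and -4.45), while Amhr2, the receptor of anti-Müllerian hormone, was higher in Sertoli cells than in testes (2.39 ± 0.26). With testis replicate 1 or 2 left out, 0 members of these lists were called in Sertoli minus testis. Called erythroid genes of that comparison fell from 5 to 2 without either Sertoli array and to 1 without either ovary array. Those of pre-granulosa minus ovary fell from 6 to 0 without either ovary array and to 3 without either testis array.

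The early gonad list was called in neither XY minus XX comparison (adjusted p = 0.710 and 0.346), nor were erythroid (0.940 and 0.907), mesonephric (0.989 and 0.307), neural (0.546 and 0.283) or TGF-beta, BMP and activin genes (0.971 and 0.177). X-linked genes that escape inactivation were not called as a list in either (adjusted p = 0.645 and 0.907), nor were ribosomal protein genes (0.736 and 0.715) or widely used reference genes (0.989 and 0.889). Neurofilament genes Nefl and Nefm were lower in pre-granulosa cells than in ovaries (-2.03 ± 0.26 and -2.01 ± 0.15), and the mesonephric gene Cdh16 was higher in Sertoli cells than in testes (2.52 ± 0.23).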
